A study of Fragaria vesca with 3 samples.

How the data were processed

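Genomic DNA of wild-type Fragaria vesca fruit at 30 days post anthesis was profiled by DNA affinity purification sequencing with FvSEP3, in 2 IP replicates and 1 input library. The labels gave each sample's group and replicate number. Nothing in the labels says that the IP replicates came from separate plants beyond calling them biological replicates. The analysis used 3 deposited tables, namely a peak list for each IP replicate and a merged list of the series. No list of the input sample was used here, and 1 column of the merged list, the mean −log10 q, was not used.

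Reads were aligned with BWA and peaks were called with MACS2, per the submitters' processing notes, with versions and settings not given in the sources used here. Peaks were listed per replicate, per the file headers. Each peak carried −log10 p-values and −log10 q-values of the peak caller, as deposited by the authors, and a fold enrichment, the ratio of signal to background that the authors deposited for each peak. The merged list gave the authors' mean of both replicates for these values, per the file headers, and a test on the file showed that each mean fold equalled the average of the replicate values. Across both replicate lists 0 peaks had a fold enrichment under 2 and 0 had a −log10 q under 3. The genome build is not given in the sources used here. The lists used 7 chromosomes and 8 contigs. Gene assignment, position class and distance to the gene start were the authors' deposited annotation. Of the exon and intron peaks, 633 in replicate 1 and 729 in replicate 2 were assigned to a gene other than the one they lay in.

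Gene names are the descriptions in the lists. The reference table supplied with the data, of assembly FraVesHawaii_1.0, matched the protein identifiers of 10701 of the 18238 genes, carried no descriptions and was not used for positions.

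Calculations used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and the overlap code was checked against bedtools 2.31.1, with 13597 replicate 1 peaks shared by either. A peak was shared if it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 100 random placements of the replicate 2 peaks, with the largest peak end on each sequence standing in for its length. Fold enrichment was used only to rank and describe peaks within a list, and a mean ± SD over the pair of replicates describes the 2 deposited values. Intervals of shares cover counting error only. A promoter peak had a deposited distance from −2000 to 0 bp. Genes with a promoter peak in each list were intersected, and the expected overlap was the product of both shares among genes with any peak.

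The 18 gene lists were defined by words in the descriptions, with 10 ripening lists, 5 transcription factor lists and 3 comparison lists. The words were fixed before the data were examined. After the counts under these words had been seen, wrongly matched words were removed, such as methylene from ethylene, and the corrected lists are the ones reported; the lists as first written are among the alternatives. Each list was tested with a two-sided Fisher's exact test against all other genes with any peak in either list, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The planned background of all annotated genes needs an annotation that was not used here, so the test asks about promoters among genes that have a peak. On simulated data, with all lists changed, the test called a list in a median of 0.00% of 100 simulations with no change, 68.0% at 2 times the share (25% for TCP and SBP, the lowest of all) and 98.5% at 3 times the share, over 18 lists and 18238 genes.

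Genes named in the text were chosen by a rule fixed before the data were examined, applied to the corrected lists. They were the 10 overlapping promoter peaks with the best mean rank of fold enrichment, the 3 best ranked members of each list other than the comparison lists, up to 10 MADS-box genes, and members named as MYB10, NCED, chalcone synthase, dihydroflavonol 4-reductase, polygalacturonase or pectate lyase. Other genes are said to have been chosen after their values were seen. As words were removed from the lists after counts had been seen, which list members are named may depend in part on that correction.

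The alternatives were the peaks of each list at or above its median fold enrichment, a −log10 q of at least 10, overlap of at least 50% of both peaks, midpoints within 100 bp, the merged list, each replicate alone, promoters of 1 and 3 kb, and ranking by −log10 p. Alternatives chosen after the data were seen were the lists as first written, a promoter extended 500 bp into the gene, any shared peak of a gene, chromosomes without contigs, lists without out-of-place entries, and replicate 2 peaks shifted by 10 kb. A count was taken as unchanged within 1.5 times, a share within 1 SD of the 2 replicate lists, and rho within 1 SD of the 7 chromosomes. The motif analyses, an independent gene assignment and a background matched on upstream gaps were left out because they need a genome or annotation.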

Results

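Binding of FvSEP3, a MADS-domain transcription factor, was measured by DNA affinity purification sequencing on genomic DNA from wild-type woodland strawberry (Fragaria vesca) fruit at 30 days post anthesis. In this assay a transcription factor made outside the cell pulls down fragments of purified genomic DNA, which are then sequenced and called as peaks. The 3 samples were 2 immunoprecipitation (IP) replicates and 1 input library. The IP replicate 1 list held 19298 peaks assigned to 14153 genes, and the IP replicate 2 list held 21823 peaks assigned to 15538 genes. A merged list of the authors held 13283 peaks assigned to 10674 genes. The median peak length was 303 bp in replicate 1 and 306 bp in replicate 2. Fold enrichment, the authors' own value for each peak, had a median of 3.05 in replicate 1 with a highest value of 7.21, and a median of 3.004 in replicate 2 with a highest value of 7.56. Peaks above 5-fold numbered 49 and 67. The files gave no read counts, so the depth of each library is unknown. Positions are in the coordinates of the deposited lists, whose genome build is not given in the sources used here.

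The first comparison asked how far the 2 IP replicates found the same binding sites. Of the replicate 1 peaks, 13597 (70.5%, 95% Wilson interval 69.8 to 71.1) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks, 13539 (62.0%, 61.4 to 62.7) overlapped a replicate 1 peak. The strongest shared peak lay on contig_7 in an intergenic position, assigned to FvH4_c7g00010 at 11743 bp from the gene start, with a fold enrichment of 7.21 in replicate 1 and 7.56 in replicate 2. It ranked first in both lists. Its −log10 p was 296 in replicate 1 and 352 in replicate 2. Peaks on the chromosomes, of lower fold enrichment, had medians of 11.8 and 12.3. Whether greater read depth on this contig played a part is unknown, as no read counts were held. Among shared peaks near described genes, the 5' UTR of FvH4_3g36670, scarecrow-like protein 30, on chromosome 3 from 31432972 to 31433222 reached 6.21 and 5.65. A peak in exon 7 of FvH4_2g03210 on chromosome 2 from 2458942 to 2459197, assigned to the neighbouring FvH4_2g03200 (1-aminocyclopropane-1-carboxylate oxidase homolog 1-like), reached 6.16 and 5.77. These peaks were chosen after their values were seen. Random placement of the replicate 2 peaks, repeated 100 times, gave a mean overlap of 7.05% of replicate 1 peaks and at most 7.47%. Sharing was lower among weaker peaks. With each list divided into 10 equal parts by fold enrichment, it went from 83.8% in the highest part of replicate 1 to 53.5% in the lowest, and from 80.2% to 40.9% in replicate 2. Spearman's rho of fold enrichment across the 13597 pairs of shared peaks was 0.529, a correlation across peaks, which are not independent replicates. It ranged from 0.504 to 0.539 over the 7 chromosomes. Part of the excess over random placement may come from the single input library, if both lists were called against it.

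**Figure D1:**
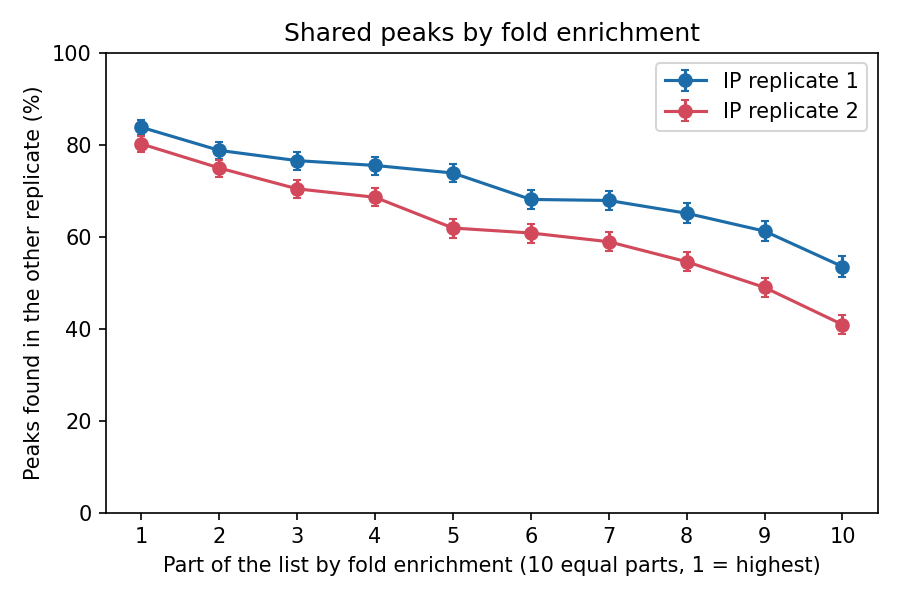
Percentage of peaks found in the other IP replicate (y axis) against the 10 equal parts of each list by fold enrichment (x axis, 1 is the highest), for both IP replicates; bars are 95% Clopper-Pearson intervals. Sharing falls from 83.8% to 53.5% in replicate 1 and from 80.2% to 40.9% in replicate 2.

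The second comparison asked where the reproducible peaks lay relative to genes. Gene bodies held 7768 of the 13597 shared peaks (57.1%), with 3545 in exons, 2434 in introns, 1265 in 5' UTRs and 524 in 3' UTRs. Promoters, defined as the 2 kb upstream of the gene start, held 2773 shared peaks (20.4%), of which 1806 lay within 1 kb. A further 2922 shared peaks (21.5%) were intergenic and 134 lay just downstream of genes. The 2 IP lists taken separately had a promoter share of 20.8% ± 0.0700 (SD, n = 2) and a gene body share of 56.1% ± 0.202 (SD, n = 2). Exons held 26.1% of the shared peaks, 20.01% of those found in replicate 1 alone and 24.3% of those found in replicate 2 alone. Around gene starts the peaks were densest inside the gene. In replicate 1, 3586 peaks lay within 500 bp downstream of the start and 1619 within 500 bp upstream, a ratio of 2.21. In replicate 2 the numbers were 4024 and 1802, a ratio of 2.23. The share of the genome in each class was not analysed here, so these shares are not set against chance.

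**Figure D2:**
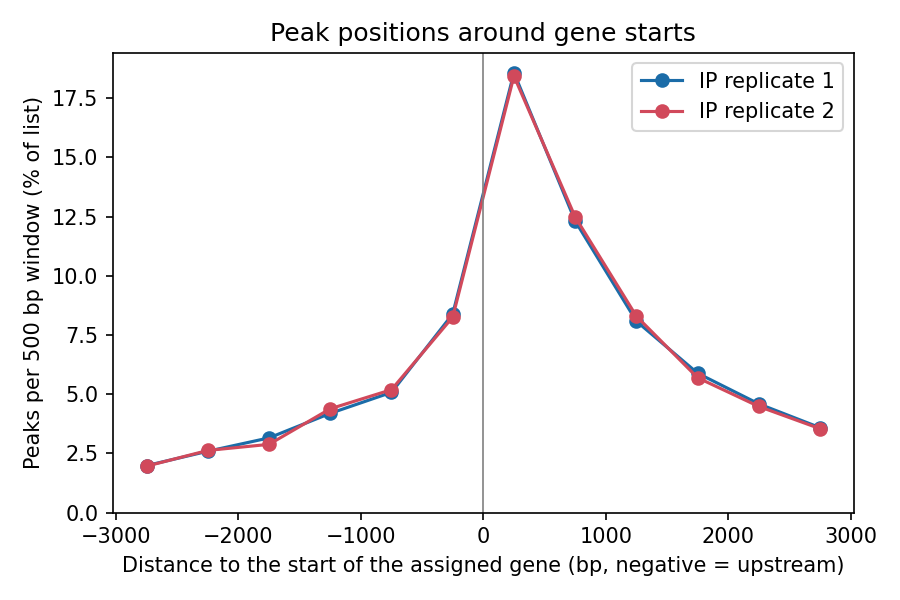
Percentage of each IP replicate's peaks (y axis) in 500 bp windows by distance to the start of the assigned gene (x axis, bp, negative values upstream); points are window values for each list. The window from 0 to 500 bp holds 18.6% of replicate 1 and 18.4% of replicate 2 peaks, against 8.39% and 8.26% in the 500 bp upstream.

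The third comparison asked which genes had a promoter peak in both replicates. There were 2495 such genes among the 18238 genes with any peak, from 3830 genes in replicate 1 and 4269 in replicate 2. Lists drawn independently from these 18238 genes would share 896 genes, so the observed number was 2.78 times as high. The 18238 genes were themselves defined by a peak in either list, so this ratio depends on that background. The strongest promoter peaks of both lists, by mean rank, lay at FvH4_3g45642, described as a probable disease resistance protein, on chromosome 3 from 37832203 to 37832465 in replicate 1. Its fold enrichment was 5.23 ± 0.191 (SD, n = 2), but the gene had no promoter peak in both replicates with reciprocal overlap, with a 1 kb promoter or in the merged list. FvH4_2g35770, a tocopherol cyclase of vitamin E synthesis, followed on chromosome 2 from 26361163 to 26361533 with 5.10 ± 0.0428 (SD, n = 2), and then FvH4_3g32880, a cytochrome P450 CYP749A22-like gene, with 5.04 ± 0.314 (SD, n = 2). The other 7 of the leading 10 were FvH4_6g02021 (protein FMP32), FvH4_5g28550 (a UPF0202 protein), FvH4_7g19390 (a plasma membrane-associated cation-binding protein), FvH4_4g07821 (beta-taxilin-like), FvH4_7g32140 (a WD repeat-containing protein), FvH4_4g14434 (a zinc finger MYM-type protein) and FvH4_6g23141, which has no description. FvH4_6g23141 had the most unequal pair of values, 6.10 in replicate 1 and 4.49 in replicate 2. FvH4_5g28550 and FvH4_7g32140 were also not kept in the merged list, the latter nor with reciprocal overlap, and FvH4_2g35770, FvH4_3g32880, FvH4_5g28550, FvH4_7g19390 and FvH4_6g23141 were not kept with a 1 kb promoter. None of these 10 genes belonged to a ripening list. The peak intervals of both replicates overlapped in 2436 of the 2495 genes, and the number of genes rose to 5010 when the first 500 bp of the gene were counted as promoter, a definition added after the data were examined.

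The fourth comparison asked whether genes of ripening pathways had promoter peaks more often than other genes, among the 18238 genes with a peak in either list. Genes without any peak are in none of the lists and not among the other genes. The shares given here and for the transcription factor families are therefore not shares of whole pathways or families. Members were matched by words in their descriptions, so a member need not act in the pathway. None of the 10 ripening lists, MADS-box among them, passed the two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 18 lists. Of all 18 lists 0 passed, and the 1 list with an unadjusted p under 0.05 was WRKY, a transcription factor list with fewer such genes. With the lists as first written, 0 passed as well, but 2 had an unadjusted p under 0.05. Beside WRKY this was flavonoid and phenylpropanoid (2 of 51, Fisher's exact p = 0.0400, adjusted p = 0.341). Across the ripening lists, 63 of 595 genes had a promoter peak in both replicates (10.6% against 13.8% of other genes) and 318 had a shared peak at any position (53.4% against 59.4%), differences that were not tested as a whole. Pectin enzymes, which take apart the pectin of the cell wall, had promoter peaks in 13 of 89 members, including FvH4_7g29640 (pectin acetylesterase 9) at 3.76 ± 0.493 (SD, n = 2) and FvH4_2g25970 (a probable pectinesterase) at 3.68 ± 0.172 (SD, n = 2). Expansins and other enzymes of wall glycans had 9 of 63, led by FvH4_5g04490 (endoglucanase 6) at 4.07 ± 0.485 (SD, n = 2), with FvH4_5g23130 (cellulose synthase-like protein D3) and FvH4_2g25990 (endoglucanase 17) next. The abscisic acid list, named for a hormone of fruit ripening, had 9 of 75. Among them were 2 genes in the list by their descriptions as protein phosphatases 2C, FvH4_2g41410 at 4.26 ± 0.553 (SD, n = 2) and FvH4_6g34170 at 4.11 ± 0.0831 (SD, n = 2). The zeaxanthin epoxidase-like FvH4_1g12581 was another. Auxin genes had 11 of 71, led by FvH4_5g38700 (auxin response factor 17) at 4.28 ± 0.555 (SD, n = 2), with FvH4_1g18900 (IAA9) and the transporter FvH4_2g01570. The ethylene list had 9 of 88. Among them were FvH4_4g08100, in the list by its description as AP2-like ethylene-responsive transcription factor AIL5, the 1-aminocyclopropane-1-carboxylate oxidase-like FvH4_2g15310 and FvH4_6g16040 (ethylene-insensitive protein 2). Sugar genes had 5 of 67, including the sucrose transporters FvH4_5g33660 (SUC4) and FvH4_2g40120 and the sucrose-phosphate synthase FvH4_6g48160. Flavonoid and phenylpropanoid genes, whose products include the red anthocyanins, had 2 of 47, the anthocyanidin 3-O-glucosyltransferase FvH4_6g39310 and the flavonoid 3'-monooxygenase-like FvH4_2g10240, against 13.7% of other genes (Fisher's exact p = 0.0569, adjusted p = 0.343). Aroma genes had 1 of 31, the NADPH:quinone oxidoreductase FvH4_7g03220, and gibberellin genes had 0 of 24. With a single replicate, 9 of the 18 lists moved by over 1.5 times in odds ratio, namely flavonoid and phenylpropanoid, gibberellin, ethylene, sugar, aroma, WRKY, TCP and SBP, proteasome and photosystem. For gibberellin, WRKY and photosystem the main odds ratio was 0, so any member with a promoter peak in a single replicate exceeds this limit. Flavonoid and phenylpropanoid genes had 9 of 47 on replicate 2 alone (19.1% against 23.4% of other genes) and 5 of 47 on replicate 1 alone (10.6% against 21.0%), with the odds ratio going from 0.280 to 0.775 and 0.447. Gibberellin genes had 5 of 24 on replicate 2 alone (20.8% against 23.4%) and 1 of 24 on replicate 1 alone (4.17% against 21.0%). On replicate 2 alone, ethylene genes turned from a lower share than other genes to a higher one, with 24 of 88 (27.3% against 23.4%) and an odds ratio of 1.23 against 0.718 in the main setting. The odds ratio also crossed 1 on replicate 2 alone for proteasome genes (from 0.728 to 1.25) and abscisic acid genes (from 0.860 to 1.03), and for TCP and SBP genes on either replicate alone (from 1.11 to 0.664 in replicate 1 and 0.818 in replicate 2). Several ripening genes named here lost their promoter peak in both replicates under an alternative. With reciprocal overlap these were FvH4_2g25970, FvH4_5g38700 and FvH4_6g16040. Among peaks of at least the median fold enrichment they were FvH4_6g16040, FvH4_2g40120, FvH4_6g48160, FvH4_6g39310 and FvH4_2g10240. At a −log10 q of at least 10 they were FvH4_6g16040, FvH4_1g12581, FvH4_5g33660, FvH4_2g40120, FvH4_6g39310 and FvH4_2g10240. With a 1 kb promoter they were FvH4_2g25970, FvH4_5g23130, FvH4_2g25990, FvH4_2g40120, FvH4_6g48160, FvH4_2g10240 and FvH4_7g03220. Lists of these sizes were also simulated with all 18 changed at once to 2 times the share of promoter-peak genes. The test called a list in a median of 68.0% of 100 simulations and in 25% for TCP and SBP, the lowest of all. The highest rate for a list was 100%. A doubling of a single list among unchanged ones was not simulated, nor was a lower share. The power of the test for those cases is unknown, and even a doubling could have been missed in many of the lists.

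**Figure D3:**
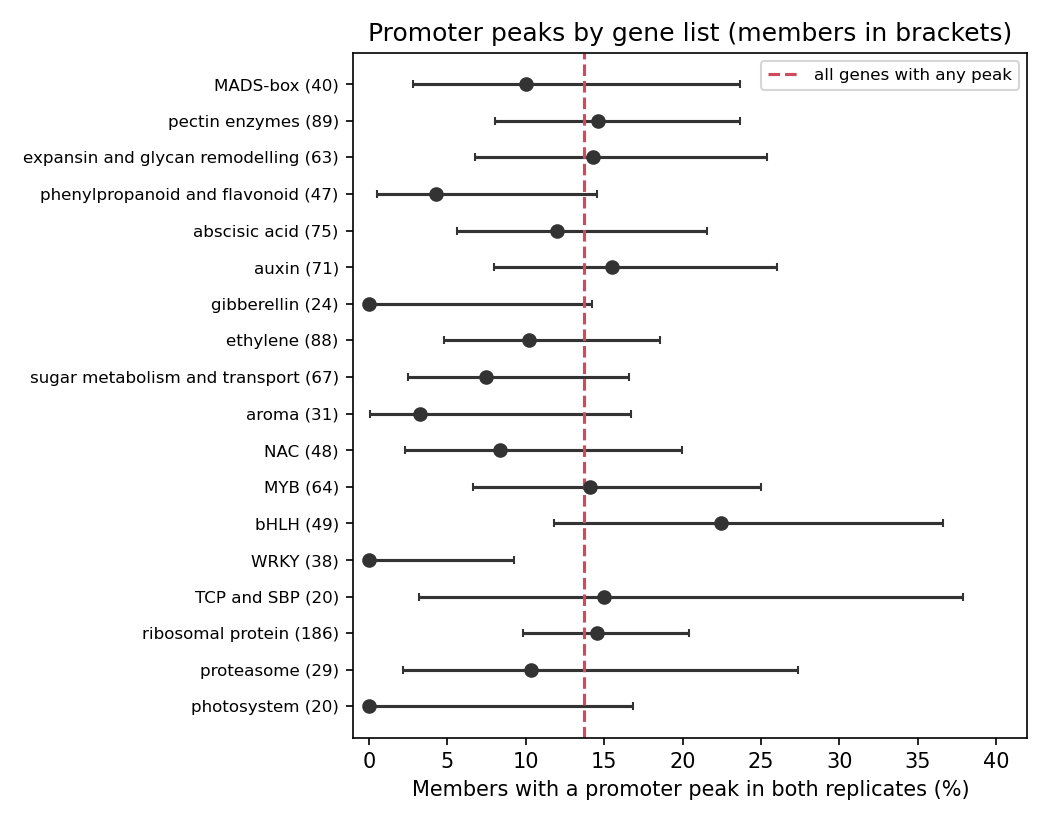
Percentage of members with a promoter peak in both IP replicates (x axis) for each of the 18 gene lists (y axis, number of members in brackets). Members are genes with a peak in either list. Bars are 95% Clopper-Pearson intervals and the dashed line is the 13.7% of all genes with any peak. No list passed the test after adjustment.

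Among transcription factor families, bHLH genes had the highest share and WRKY genes the lowest, and neither passed the test. Promoter peaks in both replicates were found for 11 of 49 bHLH genes (22.4%, Fisher's exact p = 0.0919, adjusted p = 0.343), led by FvH4_5g35810 (bHLH143-like) at 4.01 ± 0.315 (SD, n = 2), FvH4_4g28130 (bHLH30) and FvH4_2g04900 (bHLH113-like). With the first 500 bp of the gene counted as promoter, a definition added after the data were examined, 25 of 49 bHLH genes had such a peak (Fisher's exact adjusted p = 0.0102 over the 18 lists), and over all 234 list tests run the adjusted p was 0.132. WRKY genes had 0 of 38 (Fisher's exact p = 0.00732, adjusted p = 0.132), although 19 of the 38 had a shared peak at some position (50.0% against 59.2% of other genes). WRKY genes had 4 of 38 on either replicate alone (10.5%, against 23.4% of other genes in replicate 2 and 21.0% in replicate 1), and 9 of 38 with the first 500 bp of the gene added (23.7% against 27.5%). MYB genes had 9 of 64, with FvH4_5g14970 (myb-related protein 306-like) at 3.93 ± 0.0604 (SD, n = 2), FvH4_2g33810 (MYB44-like) and FvH4_3g00080 (APL-like) first. NAC genes had 4 of 48, with FvH4_7g18210, FvH4_5g00351 and FvH4_6g23470 ranking highest, and TCP and SBP genes had 3 of 20, namely FvH4_4g23650, FvH4_5g15150 and FvH4_7g10680, the first of them not kept with reciprocal overlap or in the merged list. The comparison lists gave 27 of 186 ribosomal protein genes (14.5%), 3 of 29 proteasome genes and 0 of 20 photosystem genes. MADS-box genes, the family of FvSEP3 itself, had promoter peaks in 4 of 40 members (against 13.7% of other genes, Fisher's exact p = 0.647, adjusted p = 0.866). The odds ratio of 0.701 turned to 1.08 in the merged list (6 of 40), 1.06 with a 3 kb promoter (7 of 40) and 1.42 with 500 bp of the gene added (14 of 40). In all, 8 of the 18 lists had an odds ratio on the other side of 1 in at least 1 of 11 promoter alternatives, namely MADS-box, expansin and glycan, abscisic acid, ethylene, MYB, TCP and SBP, ribosomal protein and proteasome. The 4 MADS-box genes with a promoter peak in both replicates were FvH4_5g08530 (MADS-box transcription factor 23-like) at 3.43 ± 0.184 (SD, n = 2), FvH4_5g34740 and FvH4_2g40280 (both described as AGL61) and FvH4_6g35690 (AGL62). The last 3 were not kept among peaks of at least the median fold enrichment, at a −log10 q of at least 10 or with a 1 kb promoter. Among the other families, FvH4_5g15150, FvH4_7g10680 and FvH4_6g23470 were not kept under the first 2 of these settings, and FvH4_7g10680, FvH4_2g33810, FvH4_3g00080, FvH4_7g18210 and FvH4_5g00351 were not kept with a 1 kb promoter. The descriptions name no gene as FvSEP3, so its own gene is not reported.

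The gene names fixed before the data were examined gave mixed results. A polygalacturonase-like gene, FvH4_1g26930, had a promoter peak on chromosome 1 from 18725759 to 18726092 at 3.46 ± 0.0288 (SD, n = 2), not kept with a 1 kb promoter, and a probable pectate lyase 8, FvH4_4g05760, had one on chromosome 4 from 5136646 to 5136858 at 3.35 ± 0.0223 (SD, n = 2). NCED enzymes carry out a committed step of abscisic acid synthesis. FvH4_4g05900 (NCED6) had a promoter peak on chromosome 4 from 5280859 to 5281416, at 3.68 in replicate 1 and 2.34 in replicate 2, which was not kept in the merged list, among peaks of at least the median fold enrichment or at a −log10 q of at least 10. FvH4_3g05440 (NCED1) had a single peak, in its exon, in replicate 2. For FvH4_3g16730 (NCED3-like), the replicate 1 list held only an intergenic peak at −4114 bp from the start, at chromosome 3 from 10560259 to 10560676 with a fold enrichment of 2.90. The replicate 2 list held only a promoter peak, from 10564318 to 10564557 with 2.88. The authors' merged list gave both peaks for both replicates, so a promoter peak of this gene in both replicates rests on the merged list. FvH4_2g02110, described as chalcone synthase, the first enzyme of the flavonoid pathway, had no promoter peak but a shared peak in exon 2. This peak lay on chromosome 2 from 1766157 to 1766419, at 3.21 in replicate 1 and 2.87 in replicate 2. Genes were matched by description, so a gene of this enzyme under another description would not be counted here. The dihydroflavonol 4-reductase-like gene FvH4_6g45521 had a promoter peak in replicate 2 alone at 3.58, and FvH4_2g30320, described as MYB10-2, had only intergenic peaks, in replicate 2.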

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

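The tests with a promoter extended into the gene, any shared peak, chromosomes alone, first-written lists and lists without out-of-place entries were chosen after the data were seen. No paired analysis was possible because the design holds 1 group of IP replicates and no contrast. Not run were 14 alternatives on motifs, gene assignment and matched background, which need a genome or annotation. Of 66 comparisons with an alternative, 32 stayed within the limits. The limit was 0.0700 points for the promoter share and 0.202 points for the gene body share, so very small shifts counted as beyond it. For the share of peaks found in the other list it was 5.95 points, the SD of the 2 shares of the same overlap. It does not measure a spread between repeated experiments, so the tally says little about robustness. By construction, fewer peaks remained in the higher-fold part of the lists (9649 and 10912) and at a −log10 q of at least 10 (8878 and 11219). Both lists were cut before they were compared, so a peak whose partner fell under the cut counted as not shared. Against the whole other list, stronger peaks were shared more often than weaker ones. With both lists cut to the higher-fold part, 57.5% of replicate 1 and 50.7% of replicate 2 peaks were found in the other list. The share was 60.7% and 47.9% at the stricter q. It was 63.3% and 56.0% with reciprocal overlap, and 59.9% and 53.0% with midpoints within 100 bp; shifting replicate 2 by 10 kb left 8.05% of replicate 1. Rank agreement stayed within its limit throughout. The promoter share was 20.1% in the merged list, 20.2% in the higher-fold part, 20.5% with reciprocal overlap, 20.7% to 20.8% with a single replicate, 20.5% on chromosomes alone, and 13.3% and 24.8% for 1 and 3 kb. The gene body share was 57.5%, 56.6%, 56.9%, 56.0% to 56.3%, 57.5% and, for 3 kb, 56.0%. Genes with a promoter peak numbered 1049 in the higher-fold part, 1010 at the stricter q, 3830 to 4269 with a single replicate, 1574 for 1 kb and 5010 with 500 bp of the gene added. Of 49 named genes, 27 kept a promoter peak in both at 1 kb, 36 at the stricter q and 44 in the merged list. No list passed in 11 of 12 alternative settings; 1 list, bHLH, passed when 500 bp of the gene were added (25 of 49 members, 51.02% against 27.4%, odds ratio 2.76, Fisher's exact adjusted p = 0.0102 over the 18 lists). Over all 234 list tests, main setting included, its adjusted Fisher's exact p was 0.132 and 0 passed; the odds ratio of bHLH ranged from 1.62 to 2.76 over the settings. Apart from the effects of the cuts given above, the cause of these changes was not tested. Read depth is unknown, so what it limits is open.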

Other observations

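All tests in this part were chosen after the results were seen. So were the genes it names, apart from FvH4_3g16730 (NCED3-like), which the rule fixed before had already named. Of the 40 MADS-box genes with a peak in either list, 27 had a shared peak at some position. This was 67.5% against 59.2% of other genes with a peak (p = 0.335, adjusted p = 0.604, two-sided Fisher's exact test with Benjamini-Hochberg adjustment). Genes without any peak are not counted, so these are not shares of whole families. By this measure 0 of the 18 lists passed, and 2 had an unadjusted p under 0.05, both with a lower share than other genes. These were aroma (12 of 31, 38.7%, Fisher's exact p = 0.0269) and pectin enzymes (43 of 89, 48.3%, Fisher's exact p = 0.0400), each with an adjusted p of 0.305. FvH4_4g23530, described as transcription factor MADS-box 2, had 3 peaks in its 5' UTR in each replicate. The first, on chromosome 4 from 25998769 to 25999251, had a fold enrichment of 3.72 in replicate 1 and 3.52 in replicate 2. FvH4_6g37880, described as AGAMOUS, a floral organ identity gene, had a shared peak in intron 2 on chromosome 6 from 29836208 to 29836579, at 2.41 and 2.69. A scan of 68 families named by the descriptions found 0 that passed for promoter peaks in both replicates, with 5 at an unadjusted p under 0.05, and 0 for the 10% of shared peaks with the highest fold enrichment, again with 5.

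Peaks on contig_1 and contig_3 had very small p-values at ordinary fold enrichment. These contigs held 18 of the 20 smallest p-values in each replicate list. Genes assigned there included NADH dehydrogenase subunits on contig_1 and chloroplast genes on contig_3. At fold enrichments from 2.5 to 3.5, the median −log10 p was 10.8 times that of the chromosomes in replicate 1 and 11.2 times in replicate 2. The median fold enrichment was at most 2.57 on these contigs, against 3.05 and 3.01 on the chromosomes. These values argue against higher fold enrichment as the source of the small p-values, for the called peaks on these contigs. Fold enrichment is known for called peaks alone, so the rest of the contigs is not covered. Greater read depth, as organelle DNA present in many copies could give, stays open because no read counts were held. No biological explanation was tested.

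In the merged list, 4 entries at 3 genes carried peak names of another scheme. The genes were FvH4_3g16730 (NCED3-like, 2 entries), FvH4_2g04750 (a GH3.1 indole-3-acetic acid-amido synthetase) and FvH4_7g01160 (polyketide synthase 1). Their peak numbers exceeded the place in the replicate list by a nearly constant factor, 2.21 to 2.25 in replicate 1 and 2.05 to 2.07 in replicate 2. The highest ratio was at most 1.02 times the lowest, so the names may come from a longer list in the same genomic order. Of their 8 replicate intervals, 3 occurred in the replicate lists, all 3 out of genomic order there, against 13279 of 13279 for the other entries. Of the 5 others, 2 overlapped a list peak with the same fold enrichment and other boundaries, as boundaries redrawn in the merging would leave, and 3 overlapped no peak of the lists used here. Redrawing an overlapping peak of these lists therefore cannot account for those 3 intervals. Redrawn boundaries stay open for the other 2, as does which list the entries came from, and no biological explanation was tested.

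The excess of peaks just inside gene starts was not made by weak peaks alone. Among the 10% of each list with the highest fold enrichment, the ratio of peaks within 500 bp downstream to those within 500 bp upstream was 2.33 in replicate 1 and 2.41 in replicate 2. Base composition and mappability near gene starts were not analysed here and stay open, as does a preference of FvSEP3 itself.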
